A study of Drosophila melanogaster with 6 samples.

How the data were processed

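RNA from the brains of third-instar female Drosophila melanogaster larvae was measured on 6 Agilent one-colour expression arrays, 3 from the w1118 control stock and 3 from the Bx7 mutant, per the labels. Bx7 lacks a 2 kb fragment of Beadex (Bx), which encodes a LIM-only protein. Per the labels' protocols, total RNA was extracted with Trizol, 500 ng was reverse transcribed with an oligo dT primer carrying a T7 promoter, and Cy3 was built into the cRNA. Nothing in the labels says whether the replicates of a group came from separate sets of larvae, so p-values measure the spread between these samples, which may be technical.

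The deposited scanner files hold the intensity of each spot. Per the file headers they were written by Agilent Feature Extraction 10.7.3.1, with background subtraction, spatial detrending, surrogate values for spots not above background and no normalization between arrays. The series' value table holds log2 values, deposited by the authors with scale and centring not given in the sources used here. Set against the scanner files, each column correlated with log2 processed intensity at an r of 0.999 or more and differed from it by a shift close to the array's 75th percentile. After that shift, between 98.4% and 98.9% of probes were equal within 0.01. Column medians of this table lay at -4.37, -4.17 and -4.04 for control replicates 1 to 3 and at -4.23, -4.18 and -4.11 for mutant replicates 1 to 3. The values are single-channel levels, so the table sets no direction of comparison.

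Each array carried 45020 spots, of which 43603 were not control spots, for 32162 probes. Spots with a non-uniformity or population outlier mark were left out, 78 to 164 per array, and saturated spots were kept. The spots of a probe were averaged on the log2 scale and each array's 75th percentile was subtracted. A probe was tested when it was well above background on at least 3 of the 6 arrays, in whichever group. Probes were named through the Release 6 gene table, used for names only: 17671 probes by symbol, 4125 by a synonym or locus tag and 237 by accession. Name and accession pointed to different genes for 58 probes and to several genes for 4, and 10067 probes, among them expressed sequence tags and contigs, had no match. These were left out of the gene counts. One gene with a symbol of letters and digits in brackets is given by its locus tag, CG8799. In all 13179 genes were named on the array, and 10207 were tested, each through its tested probe with the highest mean over the 6 arrays. Coordinates are those of the probes on dm3 (BDGP release 5), as the files give them. Transcript structures and the sequence of that build were not used here, so the exon or UTR under a probe is not stated.

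Groups were compared with limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table for reading, using lmFit and eBayes with Benjamini-Hochberg adjustment over all genes tested. The threshold was an adjusted p under 0.05, and changes are log2 differences, mutant minus control, with the fit's standard error. Where every array of a group was not well above background, the change is given as a bound, "at least N-fold". For that bound the bright group's mean was set against the mean, over the dim group's arrays, of the higher of the lowest signal among probes well above background and the probe's own signal. Such a bound holds for the processed signal alone and carries no sampling error. The lowest signal used for it is not a detection limit, since probes with higher signals can fail to be well above background. On mutant replicate 1 that lowest signal was -8.80, yet the Bx probe at X:18415187 to 18415246 read -6.71 without being well above background. The bounds are therefore cautious readings of the fitted change and not strict lower limits for the RNA. The change under another background correction can lie below it. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Called genes were compared by position with Fisher's exact test, two-sided, 4 tests adjusted together. A single value over 3 against 3 arrays was tested with an exact permutation test, whose smallest p is 0.1. The number of arrays limits the precision of all values. Control and mutant are different stocks, so the deletion in Bx and other differences between the stocks cannot be told apart in this design.

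The design, the alternatives, the gene lists and the rule for named genes were set before the data were examined. The rule named Bx, the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap and whose tested probes all had the same sign, and up to 4 members past the threshold of each list. Of a list with none past it, up to 2 members with the smallest p are given as values. The 39 lists held 1161 names, of which 1140 matched a gene and 995 list entries were tested.

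The arrays lay on 2 slides, each scanned together. Slide 1 held replicates 1 and 2 of both groups and slide 2 held replicate 3 of both. Slide was tried as a fixed and as a random block, with slide 1 alone as a further alternative. Other alternatives were quantile normalization, the array median, normexp background correction with an offset of 50, other filters on dim probes, the mean of a gene's probes, outlier-marked spots kept, the replicate number as a block, eBayes with trend and robust, the series' value table, and each array left out in turn.

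The fit was tested on simulated data, 5 runs of 10207 genes with the real gene means, the residual spreads reassigned among genes and 50 genes changed at each size. Of genes changed by 0.5, 1, 2 and 4 on the log2 scale, 12.8%, 64.0%, 87.2% and 95.2% were recovered, with 7.2 false calls per run. A shift of 0.5 in the detoxification list was found in 5 of 5 runs. Genes were simulated as independent, whereas the estimated correlation within this list was 0.17 in the real arrays. These runs therefore do not test whether camera's preset correlation of 0.01 is suitable.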

Results

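Gene expression was measured in the brains of third-instar female larvae from the w1118 control stock and from the Bx7 mutant of Beadex (Bx), with 3 arrays per group. Bx encodes a LIM-only protein that binds the LIM-domain cofactor Chi, and the comparison asked which transcripts of the larval brain differ in the mutant. Between 63.2% and 71.3% of the probes on an array were well above background, and the 75th percentile of the processed intensity lay between 1885 and 2426. Correlations across the 10207 genes tested were 0.979 to 0.985 between control arrays, 0.987 to 0.992 between mutant arrays and 0.965 to 0.973 between groups. These are correlations across genes, which are not independent replicates. The first principal component held 54.5% of the variance and parted the groups. The second held 19.1% and parted the slides. On it control replicate 3 and mutant replicate 3, the arrays of slide 2, lay at -32.8 and -19.9. The arrays of slide 1 lay between 5.64 and 25.1. The main fit held no term for slide. The male-specific dosage compensation RNA roX2 (lncRNA:roX2) was well above background on control replicates 1 and 2 and on mutant replicate 2, and on none of the other 3 arrays, although all samples are labelled female. The related RNA roX1 (lncRNA:roX1) was well above background on all 6 arrays. Its brightest probe read from 1.09 (control replicate 3) to 2.56 (control replicate 1). The 3 arrays without roX2 are therefore not shown to be free of male RNA.

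Bx itself was read by 3 probes. The probe at X:18465505 to 18465564 (dm3) was well above background on all 6 arrays, with a normalized log2 level of -0.0016 ± 0.28 (SD, n = 3) in controls and 0.24 ± 0.46 (SD, n = 3) in mutants. The difference of 0.24 ± 0.27 (SE) was smaller than the spread between arrays, with a limma adjusted p of 0.72 and a 95% interval from -0.41 to 0.90, or 0.753-fold to 1.86-fold. The exact permutation p was 0.6. The probe at X:18460469 to 18460528 was not well above background on any array. The probe at X:18415187 to 18415246, which carries the name CG15048 on the array, was so on 1 control array only. The labels do not place the deleted 2 kb fragment, so the measurable probe may lie outside it and then checks nothing about the genotype.

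**Figure D1:**
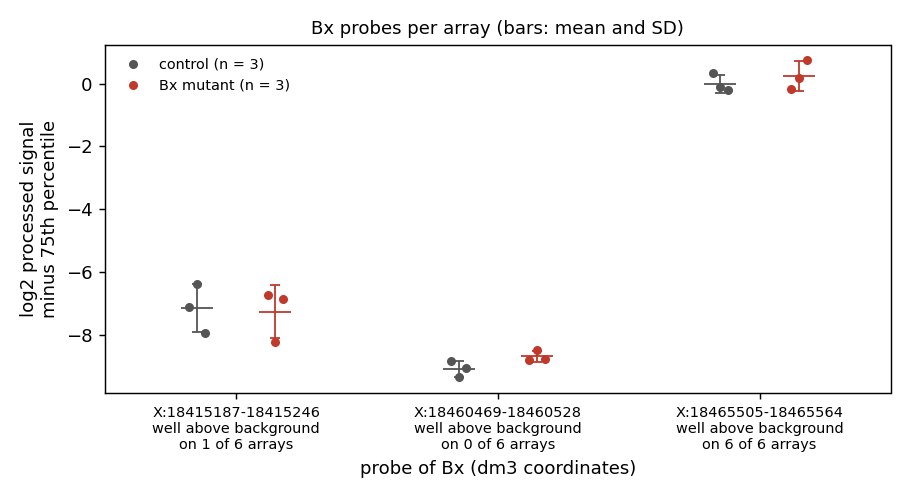
Normalized log2 signal (vertical axis, log2 processed signal minus the array's 75th percentile) of the 3 Bx probes (horizontal axis, dm3 position) on 3 control and 3 Bx mutant arrays. Points are arrays, bars are mean and SD; at the only probe above background on all 6 arrays the groups overlap, with means of -0.0016 and 0.24.

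The mutant brains differed from the controls at 814 of the 10207 genes tested (7.97%), 344 higher and 470 lower. Of these, 478 changed at least 2-fold, 210 upward and 268 downward by the fitted change. The controls gave no signal well above background for 25 of the genes that rose, and the mutants gave none for 69 of the genes that fell. All 814 genes had mutant values entirely above or below the control values, as had 2741 genes in all (26.9%, where chance gives 10%). With slide as a block 849 genes passed (360 higher, 489 lower). Within slide 1 alone 484 passed, and 454 of these (93.8%) had the same sign in the single pair on slide 2, where no test was possible, against 60.7% of all genes. Without control replicate 2 the count was 518, and without mutant replicate 1 or 2 it was 421 in either case. Under normexp background correction 230 passed, and without the 3 arrays that read roX2 above background, which leaves 1 control and 2 mutants, 5 passed. In the latter fit the 814 genes had a median of 0.967 of their change over all 6 arrays. These genes were called with the same arrays, and every choice of 1 control and 2 mutants gave 0.960 to 1.03. The value therefore says nothing about the arrays that read roX2.

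Among the 12 largest rises 7 were in genes that were not well above background on any control array at the tested probe. NT5E-2, a 5'-nucleotidase gene (2R:13380595 to 13380654), was at least 97.5-fold higher in mutants, with a limma adjusted p of 1.41e-05. Sod3, an extracellular superoxide dismutase gene (2R:7268078 to 7268137), was at least 84.5-fold higher at this probe (adjusted p = 6.61e-06). A brighter Sod3 probe (2R:7268830 to 7268889) was not tested, since 1 of its spots on a mutant array was marked as an outlier. It lay at -0.17 ± 0.36 (SD, n = 3) in controls and at a mean of -0.16 on the 2 unmarked mutant arrays. With that spot kept, or in the series' value table, this probe stood for the gene and Sod3 did not pass (log2 change 1.27 in either, highest adjusted p 0.606). The cytochrome P450 gene Cyp4e1 rose at least 25.9-fold, CG18095 at least 28.3-fold, CG8851 at least 13.8-fold, Jhbp15 at least 10.2-fold and the Bomanin immune peptide gene BomBc3 at least 8.25-fold. These are the 7 genes at background in the controls. Actbeta, which encodes an activin ligand, rose by 5.72 ± 0.22 (SE) on the log2 scale, with 2 of 3 control arrays above background. CG4593 rose by 5.67 ± 0.16, CG15046 by 4.45 ± 0.42 and CG32650 by 4.27 ± 0.13. The heparan sulphate sulphotransferase gene sfl rose by 4.51 ± 0.61, from -5.83 ± 1.21 (SD, n = 3) to -1.32 ± 0.45 (SD, n = 3). These 4 were above background on all 3 control arrays. CG15046 lies at X:18382181 to 18382240, close to the Bx probes. Under normexp background correction 11 of these 12 rises did not pass, CG4593 being the exception. The log2 changes were then 3.03 for NT5E-2 (adjusted p = 0.113), 2.76 for Sod3 (0.133), 2.98 for Actbeta (0.0722), 2.74 for CG15046 (0.067), 2.42 for sfl (0.0929), 2.01 for CG32650 (0.179), 1.46 for Cyp4e1 (0.426), 1.38 for CG18095 (0.468), 0.69 for CG8851 (0.690), 0.38 for Jhbp15 (0.829) and 0.29 for BomBc3 (0.863).

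The falls were larger still. CG1309 (3L:4261578 to 4261637) dropped from 3.16 ± 0.11 (SD, n = 3) to -7.19 ± 0.99 (SD, n = 3), a log2 change of -10.35 ± 0.47 (SE) with a limma adjusted p of 0.000183, and was above background on 2 mutant arrays. The P450 gene Cyp6a17 (2R:10763005 to 10763063) was at least 791-fold lower in mutants (adjusted p = 6.61e-06). Su(P) fell by 8.85 and the methuselah-like receptor gene mthl8 by 7.38, each above background on 1 mutant array. Tektin-C, which encodes a ciliary microtubule protein, fell by 8.22 ± 0.12 with all 3 mutant arrays above background. CG6000 was at least 85.7-fold lower, CG32115 at least 54.8-fold, CG8799 (2R:5282523 to 5282582) at least 27.8-fold and CG31220 at least 20.8-fold. For CG8799 the bound equals the fitted change, since its mutant signals lay above the lowest signal among probes well above background. The gustatory receptor gene Gr61a fell by 5.14 ± 0.39, with 1 mutant array above background, and CG12239 by 4.94 ± 0.18. MED11, a Mediator subunit gene, fell by 5.6 ± 1.0 with a mutant SD of 2.11, and no longer passed with any of control replicates 1 to 3 or mutant replicates 1 and 2 left out (highest adjusted p 0.091). Each of the other 23 genes in these 2 groups passed with every array left out in turn. Under normexp correction CG8799 changed by -2.16 and did not pass (adjusted p = 0.0558). All 24 were read by 1 tested probe, except BomBc3, whose 2 probes rose by 1.45 and 4.06.

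**Figure D2:**
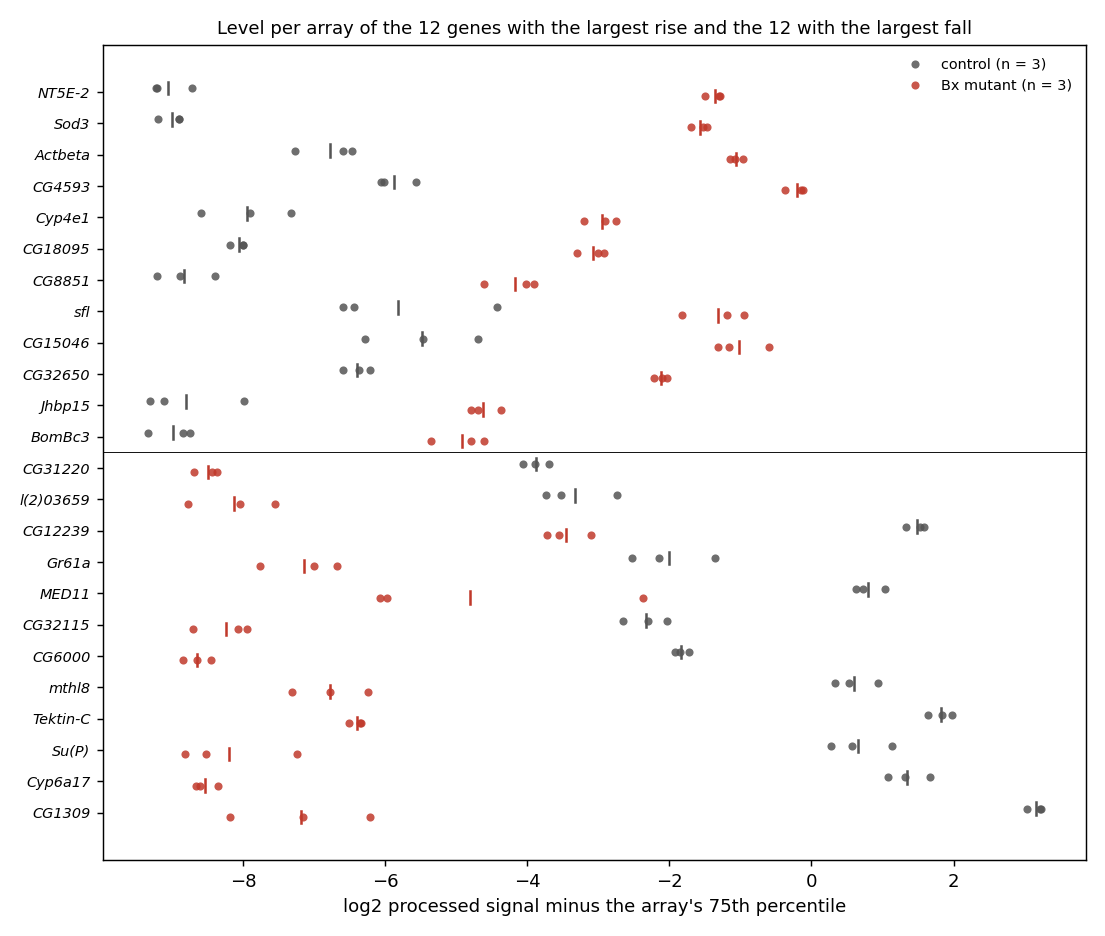
Normalized log2 signal (horizontal axis) per array of the 12 genes with the largest rises and the 12 with the largest falls (vertical axis), in 3 control (grey) and 3 Bx mutant (red) arrays. Points are arrays and short lines are group means. The groups do not overlap for any of the 24 genes because the rule that chose them required this.

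No list of transmitter genes passed camera's test. By fry's mixed test, which counts changes in either direction, the adjusted p was 1.54e-05 for dopamine and 7.87e-07 for GABA and glutamate. It was 0.00214 for neuropeptides, 0.536 for serotonin and octopamine, 0.311 for cholinergic genes and 0.218 for neuropeptide processing. The mixed test called 28 of the 39 lists, so a call by it does not set a list apart from most others. Of all genes tested, 7.97% passed the threshold. In the dopamine list 1 of 13 tested genes passed: the dopamine transporter gene DAT fell by 1.36 ± 0.11 (SE, limma adjusted p = 0.00155), and its 3 probes fell by 0.32 to 1.36. In the GABA and glutamate list 1 of 23 rose and 3 fell. Gad1, the GABA-synthesizing decarboxylase gene, fell by 1.42 ± 0.27, and the metabotropic glutamate receptor gene mGluR fell by 1.30 ± 0.14. The glutamate receptor subunit gene GluRIIC fell by 0.48 ± 0.08, and the GABA-B receptor gene GABA-B-R2 rose by 0.69 ± 0.10 at its brightest probe while its other probe changed by -0.14. Adjusted over the list alone, 1 rose and 4 fell. Among these, mGluR and DAT passed with every array left out, whereas GluRIIC lost its call with any array left out (highest adjusted p 0.104), Gad1 without control replicate 1 or any mutant replicate (0.114) and GABA-B-R2 without mutant replicate 1 or 2 (0.065). Under normexp correction Gad1 (adjusted p 0.0523), GABA-B-R2 (0.0599) and GluRIIC (0.598) did not pass, and over the mean of its probes GABA-B-R2 changed by 0.27 (0.214). In limma none passed among 14 serotonin and octopamine genes (Tbh 0.68, adjusted p = 0.0558; Oamb 0.34), 16 cholinergic genes (nAChRbeta1 0.49, ChT -0.39), 33 neuropeptide genes (Nplp4 -2.23, Lk 0.37) and 9 neuropeptide processing genes (Fur2 -0.21, amon -0.13). At an unadjusted p under 0.05 these 4 lists counted 2, 2, 6 and 0 genes. The camera adjusted p of the 6 lists, from dopamine on, lay at 0.891, 0.350, 0.715, 0.491, 0.891 and 0.669, and the other 5 counts adjusted over the list alone were as over all genes.

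Neuronal and synaptic lists held few genes past the threshold. Of 27 synaptic vesicle genes, Nsf2, an N-ethylmaleimide-sensitive fusion factor gene, fell by 1.32 ± 0.15 (SE) and was the only one past the threshold. The list's median was -0.15 with a camera adjusted p of 0.0579, but it passed with slide as a block (0.0406), and its adjusted p with an estimated correlation was 0.976. Of 30 ion channel genes, the potassium channel gene Irk2 rose by 1.71 ± 0.19, alike at its 2 probes, and the calcium channel subunit gene Ca-beta fell by 1.13 ± 0.13 at its brightest of 8 probes, which ranged from -1.13 to 0.38 (camera 0.669). These 3 genes passed with every array left out, but over the mean of its probes Ca-beta changed by -0.34 and did not pass (adjusted p = 0.139). Of 16 pan-neuronal genes jus rose by 0.60 (camera 0.891), and it lost its call in all leave-one-out fits but that without control replicate 2 (highest adjusted p 0.138). The clock gene per rose by 0.94 ± 0.18, with its 3 probes between 0.79 and 1.21, as the only one of 11 clock genes past the threshold (camera 0.203). It lost its call without control replicate 2 or any mutant replicate (highest adjusted p 0.123). Neither jus nor per passed under normexp correction (0.0749 and 0.289) or over the mean of the probes (0.554 and 0.071). In limma none passed among 22 mushroom body and learning genes (Mef2 0.91, adjusted p = 0.0562; Fas2 0.35), 26 optic lobe genes (tll 0.28, gcm 0.43) and 26 glial genes (Gat -1.01, adjusted p = 0.0614; GLaz -0.42). At an unadjusted p under 0.05 they counted 4, 3 and 8 genes, and their camera adjusted p was 0.669, 0.350 and 0.658. Adjusted over the list alone, the counts of these 7 lists were the same as over all genes tested.

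A further set of lists was tied to the Bx protein itself. In limma none of 13 genes in the list named after the LIM-domain complex passed, with 1 at an unadjusted p under 0.05 (Lmpt -0.56, adjusted p = 0.109; Lim3 0.28; camera 0.938). None of 8 genes of signalling by the receptor Alk did either, with 0 at that level (drk 0.18, Raf -0.15; camera 0.891). Of 16 wing targets linked to the gene, Dad, an inhibitor of BMP signalling, fell by 0.78 ± 0.14 (SE) with both probes alike (camera 0.891), but lost its call without mutant replicate 1 or any control replicate (highest adjusted p 0.094) or under normexp correction (0.142). Counts adjusted over the list alone were 0, 0 and 1. The list named after the LIM-domain complex also held Lmpt, Pax and smash, whose membership of a complex with Chi was not checked.

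Signalling and growth lists gave a mixed picture. Of 24 insulin pathway genes the GTPase gene Rheb fell by 1.23 ± 0.11 (SE) at its brightest probe and the insulin receptor gene InR by 1.22 ± 0.22 (camera adjusted p = 0.985). The probes of a gene differed here, from -1.23 to 0.77 for Rheb and from -1.22 to 1.27 for InR, which averaged over its 7 probes changed by 0.33. InR lost its call without control replicate 1 or 3 or mutant replicate 1 or 2 (highest adjusted p 0.1). Of 29 neuroblast genes the orphan nuclear receptor gene svp fell by 1.13 ± 0.09, with 4 probes from -1.13 to 0.18, and numb, a Notch inhibitor, by 0.55 ± 0.09, with 5 probes from -0.55 to 0.18 (camera 0.904). Of 26 Notch pathway genes numb and BobA, which fell by 1.14 ± 0.25, passed (camera 0.669). Of 44 axon guidance and adhesion genes the integrin gene mys rose by 1.20 ± 0.10 and Sema2a by 0.71 ± 0.15, and Dscam3 fell by 0.67 ± 0.10 (camera 0.891). Of 38 cell cycle genes the kinesin gene ncd rose by 1.36 ± 0.11 and the Aurora kinase gene aurB by 0.64 ± 0.10 (camera 0.892). Of 25 ecdysone response genes ImpL1 rose by 1.97 ± 0.27 with 2 control arrays above background (camera 0.350, and 0.0172 over the mean of a gene's probes), and of 11 ring gland genes nvd, which acts in ecdysone synthesis, rose by 1.34 ± 0.27 (camera 0.669). Rheb, svp, mys, ncd and ImpL1 passed with every array left out. Over the mean of their probes Rheb changed by -0.015 (adjusted p = 0.973) and svp by -0.21 (0.359), and under normexp correction ImpL1 changed by 0.024 (0.988) and mys by 0.63 (0.226), none passing, and ImpL1 did not pass within slide 1 (0.0814). Dscam3 lost its call without control replicate 1 or mutant replicate 1 (highest adjusted p 0.078) and aurB without control replicate 1 or 3 or mutant replicate 1 (0.085). The calls of numb, Sema2a, BobA and nvd were lost in 5 of the 6 leave-one-out fits each (highest adjusted p 0.098, 0.161, 0.160 and 0.127), and numb kept its call without control replicate 1, Sema2a without control replicate 3, BobA and nvd without mutant replicate 3. Over the mean of the probes numb, Sema2a, Dscam3, BobA and aurB did not pass (adjusted p 0.155 to 0.608), nor did InR, numb, Sema2a, Dscam3, BobA and nvd under normexp correction (0.0615 to 0.191). With slide as a block Sema2a (0.0529), BobA (0.0610) and nvd (0.0563) did not pass. Adjusted over the list alone, neuroblast genes numbered 1 higher and 3 lower and axon guidance genes 1 and 1, and the other counts were as over all genes.

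The detoxification list lay lower in the mutants by camera's test with the preset correlation. Of 79 tested P450, glutathione transferase and UDP-glycosyltransferase genes 11 fell and 1 rose (2 and 16 adjusted over the list alone), with a median log2 change of -0.37 and a camera adjusted p of 0.00226, against an adjusted p of 0.976 with an estimated correlation and of 0.0802 in fry. Besides Cyp6a17, Cyp304a1 was at least 8.59-fold lower, GstE11 fell by 3.11 ± 0.30 (SE) and Ugt35C1 by 2.91 ± 0.62 with 1 mutant array above background. Under normexp correction Cyp304a1 changed by -1.47 (adjusted p = 0.276) and Ugt35C1 by -1.44 (0.188), neither passing. Ugt35C1 lost its call without any of the control replicates or mutant replicate 3 (highest adjusted p 0.135), and with slide as a block (0.0731). The gene that rose, Cyp309a1 (log2 change 1.05), was named after its value was seen. The median shift was -0.49 within slide 1 and -0.014 in the pair on slide 2, and the camera adjusted p was 0.00629 with slide as a block. In the same arrays markers of fat body and of gut also lay lower, with medians of -0.75 and -1.06.

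Markers of fat body, haemocytes and gut lay lower in the mutants by camera's test with the preset correlation. The median log2 change was -0.75 over 17 fat body genes, -0.67 over 17 haemocyte genes and -1.06 over 23 salivary gland and gut genes, with a camera adjusted p of 0.0241 for each list and of 0.976 with an estimated correlation. In fry the adjusted p was 0.109, 0.357 and 0.145. Of 10 splits of the arrays into 3 and 3, 8 (the real one included) called at least 6 lists with the preset correlation. A call by that test alone therefore does not mark a difference between the groups. Lists for ring gland, eye disc and photoreceptors, wing and leg discs, muscle, and cuticle and trachea did not pass, with medians of 0.23, 0.10, 0.02, -0.07 and 0.20. In limma no fat body or haemocyte gene passed singly over all genes or adjusted over the list alone, against 8 and 6 at an unadjusted p under 0.05 (Lsp1beta -2.42, adjusted p = 0.110; Adh -0.69; Sr-CI -1.96, adjusted p = 0.0506; vkg -0.90). The midgut protease genes Jon25Bii and Jon25Bi fell by 2.54 ± 0.39 (SE) and at least 5.47-fold, and 3 genes fell when adjusted over the list alone. Jon25Bii lost its call without control replicate 1 or 2 (highest adjusted p 0.060), and Jon25Bi in all leave-one-out fits but that without control replicate 1 (0.095). Jon25Bi did not pass under normexp correction either (0.442). Within slide 1 the 3 medians were -0.91, -0.78 and -1.44, and in the pair on slide 2 they were -0.23, -0.24 and -0.44. With slide as a block each list had an adjusted p of 0.0360. The gut list did not pass within slide 1 (0.0842) or over probes well above background on all 6 arrays (0.0621), nor the fat body list without the 3 arrays that read roX2 (0.0704). Leaving out control replicate 1, mutant replicate 1 or mutant replicate 3 ended the haemocyte call (adjusted p 0.264, 0.0774 and 0.0811), and leaving out mutant replicate 1 ended that of the gut list (0.0710). The haemocyte median was then -0.36, -0.55 and -0.60, and the gut median -0.62.

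Energy metabolism lists shifted less, in the same arrays in which fat body, haemocyte and gut markers lay lower (medians -0.75, -0.67 and -1.06). Of 17 glycolysis genes the glycerophosphate oxidase gene Gpo1 fell by 0.86 ± 0.12 (SE) and Pglym78, a phosphoglycerate mutase gene, by 0.60 ± 0.13, and the list's median was -0.26 (camera adjusted p = 0.0374, and adjusted p = 0.976 with an estimated correlation). Of 74 genes of oxidative phosphorylation 3 rose and 2 fell, with a median of -0.13 and the same pair of adjusted p-values. ND-AGGG fell by 2.35 ± 0.20 and ATPsynepsilonL by 0.90 ± 0.12. ND-51L1 was at least 4.95-fold higher, COX7AL rose by 0.72 ± 0.13 and ND-15, named after its value was seen, by 0.67 ± 0.13. Under normexp correction ND-51L1 and COX7AL had the opposite sign without passing the threshold. Gpo1, ND-AGGG and ATPsynepsilonL passed with every array left out, though Gpo1 (adjusted p 0.068) and ATPsynepsilonL (0.0571) did not within slide 1. Pglym78 passed with none (highest adjusted p 0.158), nor under normexp correction (0.0982), over the mean of its probes (0.25) or with slide as a block (0.0599), COX7AL only without control replicate 1 (0.107) and ND-51L1 only without control replicate 2 or mutant replicate 3 (0.072). Without control replicate 2 the medians of the 2 lists were -0.12 and -0.057 and neither passed (camera adjusted p 0.377 and 0.552), nor did either without mutant replicate 3 (0.150 and 0.185), and without mutant replicate 1 (glycolysis, 0.0878) or 2 (oxidative phosphorylation, 0.0751) 1 of them did not. The 2 medians were -0.32 and -0.18 within slide 1 and -0.21 and -0.048 in the pair on slide 2, with an adjusted p of 0.0434 and 0.0360 with slide as a block. Glycolysis did not pass within slide 1 (0.168) or over the mean of a gene's probes (0.131), oxidative phosphorylation did not with the array median (0.108) or normexp correction (0.247), and neither did without the 3 arrays that read roX2 (0.109 and 0.919). Adjusted over the list alone, the counts were 2 lower, and 3 higher and 2 lower.

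None of the remaining lists passed camera's test. Of 45 immune genes BomBc3 and Drsl5, a Drosomycin-like peptide gene that rose by 1.79 ± 0.25 (SE), passed (camera adjusted p = 0.965). Of 25 muscle genes TpnC4, a troponin C gene, was at least 6.60-fold higher (camera 0.945). Of 19 cuticle and trachea genes Cpr47Ef fell by 3.20 ± 0.60 with 1 mutant array above background and Lcp4 by 2.41 ± 0.46, while the list's median was 0.20 and its mean -0.52 (camera 0.892). Of 88 cytosolic ribosomal protein genes RpS19b rose by 0.90 ± 0.16 (camera 0.669). Of 14 testis and male-biased genes janB rose by 0.51 ± 0.10 (camera 0.669), and it had the opposite sign under normexp correction. Of 7 genes known to differ between laboratory stocks Cyp6a17 fell and the actin-bundling gene f rose by 2.79 ± 0.12 (camera 0.350). Under normexp correction the ribosomal and stock-related lists passed (adjusted p 0.00468 and 0.00966), as did heat shock genes (0.00591). In limma no gene passed among 21 heat shock genes (stv 0.82, adjusted p = 0.0570; Hsp68 1.83), 19 photoreceptor genes (Arr1 1.74, trpl 1.15), 17 wing and leg disc genes (ss 0.88, caup 0.28) and 13 ovary genes (del -0.70, aub -0.63), with 4, 3, 1 and 4 genes at an unadjusted p under 0.05 and camera adjusted p-values of 0.122, 0.669, 0.715 and 0.658. BomBc3, Drsl5, TpnC4 and f passed with every array left out. Under normexp correction BomBc3 changed by 0.29 (adjusted p = 0.863), TpnC4 by 0.13 (0.944) and f by 1.05 (0.516), none passing, nor did Cpr47Ef (0.158), Lcp4 (0.0783) and RpS19b (0.297), and Drsl5 did not pass within slide 1 (0.0605). The call of janB was lost in all 6 leave-one-out fits (highest adjusted p 0.129). Lcp4 kept its call only without control replicate 1 (0.106), Cpr47Ef without mutant replicates 1 or 3 (0.106) and RpS19b without mutant replicate 3 (0.104). With slide as a block Lcp4 did not pass (0.0517). Adjusted over the list alone, 2 muscle genes were higher and 1 lower, 2 cuticle genes were higher and 3 lower, 1 male-biased gene was higher and 2 lower, 1 stock-related gene was higher and 3 lower, no ribosomal gene passed, and the other counts did not differ. The median differed in sign from the mean or from the direction of the camera test in the lists for insulin signalling, serotonin and octopamine, neuroblasts, axon guidance, wing targets, cell cycle, immunity, muscle and cuticle. Over the 39 lists fry, which tests a shift on balance, called 0 after adjustment and 10 at an unadjusted p under 0.05, and its mixed test, which counts changes in either direction, called 28.

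**Figure D3:**
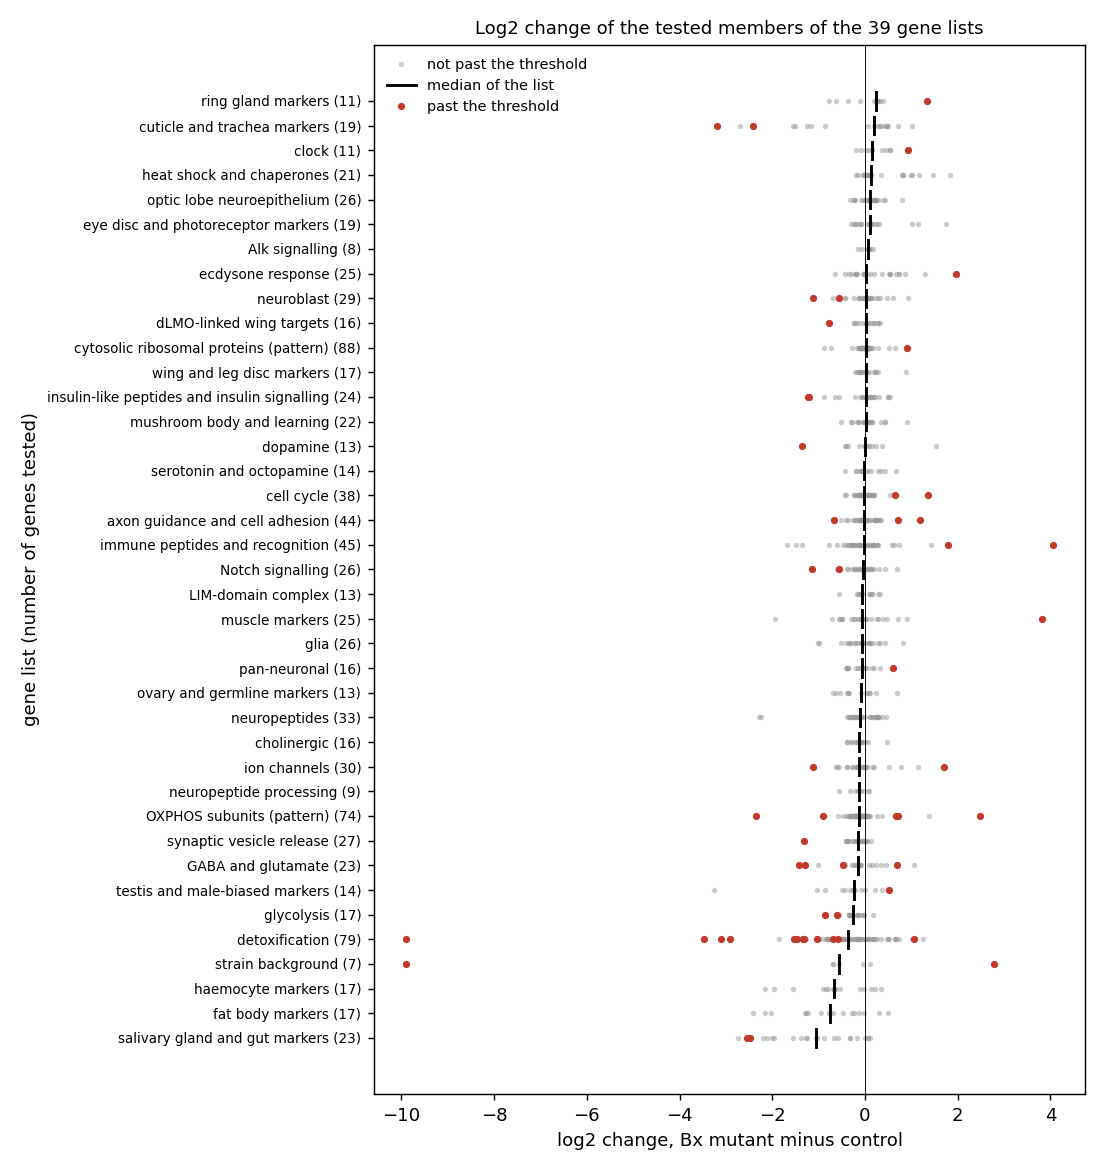
Log2 change, Bx mutant minus control (horizontal axis), of each tested member of the 39 gene lists (vertical axis, with the number of genes tested). Red points passed the threshold, grey points did not, and black lines are list medians; the lowest medians are those of gut (-1.06), fat body (-0.75) and haemocyte (-0.67) markers.

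Genes that changed lay on all chromosomes, with between 5.19% (chromosome 4) and 8.95% (2R) of the tested genes called. On the X, which carries Bx, 79 of 1691 tested genes (4.67%) rose, against 263 of 8423 (3.12%) on the autosomes, an odds ratio of 1.52 (95% interval 1.16 to 1.97; Fisher's exact test, two-sided, adjusted p = 0.00764). For genes that fell the shares were 3.73% and 4.78% (odds ratio 0.770, adjusted p = 0.0867). Within 1 Mb of the Bx probes 13 of 155 genes (8.39%) rose, against 4.30% of the rest of the X (odds ratio 2.04, adjusted p = 0.0560), and 8 fell (5.16% against 3.58%, adjusted p = 0.368). The X-linked excess of rises did not pass without control replicate 3 (odds ratio 1.36, adjusted p = 0.142), within slide 1 (1.34, 0.381), over the mean of a gene's probes (1.42, 0.0607) or under normexp correction (1.5, 0.476). Fisher's test takes genes as independent, but called genes formed 115 adjacent pairs along the chromosomes, against a mean of 64.3 for random genes. These intervals and p-values may thus be too narrow.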

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

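The count of transcripts seen in mutants only, described here, was chosen after the results were seen. The array also carries names that match no reference gene, mostly expressed sequence tags and contigs, which the gene comparisons left out. Of 4483 such names tested, 396 passed the threshold (8.83%), 175 higher and 221 lower in the mutants. Among the higher ones 19 were not well above background on any control array, which is a signal in data that no comparison of named genes used, and 42 of the lower ones were not so on any mutant array. The extremes were log2 changes of 8.05 and -7.56. With 3 arrays per group no array was tested for standing apart from its group.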

How the results depend on the processing

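Every name on the array, only genes whose tested probes share a direction, and the fit without the 3 arrays that read roX2 were chosen after the data were seen; the other alternatives were planned. Of the 65 named genes past the threshold, 41 kept their call with each array left out in turn, and the losses per array were 18, 17 and 18 for control replicates 1 to 3 and 21, 19 and 12 for mutant replicates 1 to 3. Leaving out 1 array gave 421 to 674 genes past the threshold, 173 to 307 higher and 239 to 382 lower, and an odds ratio of 1.36 to 1.84 for rises on the X. Under normexp correction 230 genes passed, 91 higher and 139 lower, 178 of them at least 2-fold, with an X odds ratio of 1.5 (adjusted p = 0.476). ND-51L1, COX7AL and janB then changed by -0.046, -0.33 and -0.36 against rises otherwise, without passing; the cause was not tested. Of the 65 named genes 35 lost their call under this correction besides these 3, among them 11 of the 12 largest rises. Slide 1 alone gave 484 genes, 215 higher and 269 lower, and an X odds ratio of 1.34 (adjusted p = 0.381), with fewer arrays. With the mean of all probes InR changed by 0.33, since its probes differ in sign, and the X odds ratio was 1.42 (adjusted p = 0.0607); the cause was not tested. With outlier-marked spots kept, rises near Bx passed (odds ratio 2.18, adjusted p = 0.0323); the cause was not tested. Every name on the array gave 761 genes changed at least 2-fold, from more names tested. Without the 3 arrays that read roX2, 1 control and 2 mutants remained, with the lone control assumed to vary like the mutants. That fit gave 5 genes, 2 higher and 3 lower, all 5 at least 2-fold, and 3 lists, and the 814 genes had a median of 0.967 of their change over all arrays; the other 8 choices of 1 control and 2 mutants gave 24 to 497 genes. Those other 8 choices had medians of 0.960 to 1.03 of the change over all arrays, in genes called with the same arrays. The median of 0.967 is therefore not particular to the arrays without roX2. The remaining alternatives kept the count of genes within 1.5 times 814, from 581 with the replicate number as a block to 1116 with every name on the array. Named genes lost numbered 3 with quantile normalization, 10 with the array median, 8 without a filter, 12 over the mean of probes, 1 with outlier-marked spots kept, 6 with slide as a fixed and 0 as a random block, 22 within slide 1, 21 with the replicate block, 3 with trend and robust and 2 in the value table. The synaptic vesicle list passed under 5 alternatives besides leave-one-out fits (adjusted p 0.016 to 0.0493). Heat shock (0.00591), ribosomal (0.00468) and stock-related genes (0.00966) passed under normexp correction and ecdysone response genes over the mean of probes (0.0172). Leaving out control replicate 1 let synaptic vesicle and heat shock genes pass, mutant replicate 1 or 2 the former, and mutant replicate 3 heat shock and ribosomal genes. Within slide 1 replicate numbers did not pair the samples: residuals of the same number correlated across genes at -0.057 and 0.119, against 0.274 for control replicate 1 and mutant replicate 2. The highest correlation, 0.318, was that of replicate 3 of both groups, the pair on slide 2. Pairs across slides lay between -0.369 and -0.021, a range that also holds the -0.057 of replicate 1 on slide 1. Residuals were centred within each group, which by itself forces some pairs to be negative. They thus followed the slide only in part. Signal over background limits the falls and rises given as bounds.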

Other observations

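The tests of distant probes, tissue markers, detoxification genes and roX2 in this part were chosen after the results were seen; the counts over other splits of the arrays were planned. Beyond the genes named so far, the detoxification genes that fell, named after their values were seen, were GstZ1 (-1.48), GstE5 (-1.35), GstT1 (-1.31) and GstS1 (-0.58), with Cyp9c1 (-1.53), Ugt302K1 (-1.03) and Cyp12e1 (-0.68). Genes past the threshold formed 115 adjacent pairs along the chromosomes among 808 placed genes, against a mean of 64.3 for random genes (permutation p = 0.0001, the smallest 10000 permutations can give).

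The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 814 genes and was the only 1 of 10 to reach that count; the highest other split gave 1. For gene lists the real split gave 6, and 8 of 10 splits gave as many, with 9 at most.

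Probes of the same gene often moved apart. In 114 genes past the threshold with a probe over 1 kb from the brightest one, the distant probes showed a median share of 0.072 of its change. Dim distant probes are argued against as the whole account, since those within 1 log2 unit of the brightest probe had a share of 0.035 (95% interval -0.115 to 0.240). A change limited to one stretch of the gene, as in 1 of several transcript forms, stays open, since in the 21 genes that also have a probe within 500 bp the near share exceeded the distant one by a median of 0.443 (95% interval 0.354 to 0.827), short of the 0.5 set for it. A sequence difference under the brightest probe alone stays open too. It was tested in 13 genes picked because their distant probes had a median share under 0.25. There, 15 probes within 500 bp had a share of 0.769 with an interval from 0.085 to 1.02. Over the 21 genes with both kinds of probe the near share was 0.774 (0.435 to 1.02), but these were not picked for distant probes that do not follow.

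Of 56 tested markers of fat body, haemocytes and gut, 83.9% lay lower in the mutants, against 50.7% of all genes. Less tissue carried over with the mutant brains stays open, since the 3 lists were picked because they lay lower; lists for ring gland (median 0.23), eye disc (0.10), muscle (-0.07) and cuticle and trachea (0.20) did not pass camera's test. The abundant markers did not fall equally, with Obp99a at -0.01, apolpp at -0.47 ± 0.18 (SE), Lsp1gamma at -1.27 and Lsp1beta at -2.42 ± 0.70, and PPO1 stands in 2 of the lists. Among the 11 detoxification genes that fell, 1, Cyp6a17, at least 791-fold lower, fell beyond the 95% interval of every marker (lowest bound -5.33, deltaTry), which argues against less tissue carried over for this gene, which also stands in the list of stock differences. The other 10 had a median of -1.41. Among these 10, Cyp304a1 (-3.48, given above as at least 8.59-fold lower), GstE11 (-3.11) and Ugt35C1 (-2.91) fell further than any marker's fitted change. The largest such marker fall was -2.73 (Jon65Ai). None of the 10 had a 95% interval beyond the lowest marker bound of -5.33, so carry-over and a change in the brain cannot be told apart. An effect of the Bx7 genotype or of the stock was not tested apart.

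The male-specific RNA roX2 read -0.32, -2.24 and -7.10 in control replicates 1 to 3 and -8.15, -3.11 and -8.17 in mutant replicates 1 to 3, a pooled SD of 3.22 that only 2 of 10207 genes exceeded. Noise of a single dim probe is argued against, since its 2 probes correlated at an r of 0.955 over the arrays. Male larvae in some of the samples may account for it and stay open, since the 6 arrays are too few. Here roX1 and roX2 had a Spearman correlation of 0.6 (exact permutation p = 0.242, two-sided) and a Pearson r of 0.794 (exact permutation p = 0.0639). Without control replicate 1 and mutant replicate 3, the 2 arrays farthest from the median roX2 level, the Pearson r was 0.859. Mutant replicate 3 had the lowest roX2 level but a roX1 level of 1.86, above the 1.48 of mutant replicate 1. The 0.859 thus leaves out an array on which roX1 did not follow roX2, and it is no check on the correlation. An effect of the Bx7 genotype on roX2 was not tested.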
